A study of Homo sapiens with 6 samples.

How the data were processed

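Ribosome profiling sequences the short mRNA fragments that ribosomes protect from nuclease digestion, so that counts per transcript and per region report where ribosomes sat. The libraries came from HCT116, a human colon cancer cell line, transduced with a lentivirus carrying Cas9 and a guide RNA and then selected in puromycin, per the labels' protocols. Guides targeted EIF5A or DOHH, or were non-targeting (NT), with 2 guides per group and 1 library per guide, which gave 6 libraries in 3 groups. Group and guide number were taken from the labels. The p-values measure the spread between libraries of different guides. The series design also names RNA sequencing, which was not used here, so a change in footprint counts was not divided into mRNA level and translation.

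The authors deposited 1 table of whole-number counts, per the file headers: for each of 9829 transcripts and each library, the counts in the 5' UTR, in the coding sequence and over the transcript. HISAT2 and GRCh38 are named in the submitters' processing notes. The counting tool, the transcript annotation, the footprint lengths kept and the treatment of duplicate reads are not given in the sources used here. The lowest value of the deposited 5' UTR and coding counts was 1 in each library, and the transcript count exceeded the sum of both regions by at least 1 in each row, so the authors either added a count of 1 to each region or set a floor at 1. The values do not tell which. Counts were used as deposited, and 1 was subtracted from each in an alternative. The count over the transcript minus the 5' UTR and coding counts is called the remainder.

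The table gives versioned Ensembl transcript identifiers and does not pair them with gene names, and the reference table given here held no Ensembl identifiers. The levels of EIF5A and DOHH transcripts, which would check the labels, were therefore not analysed here. Nor were 32 gene lists fixed before the data were examined, or the alternative without gene classes (ribosomal protein, mitochondrially encoded and histone genes). Of the named transcripts, at most 2 that were higher and 2 that were lower are printed. The rule, fixed before the data were examined, took those with the largest log2 fold change in EIF5A against NT among transcripts past an adjusted p of 0.05, with a mean of at least 50 coding counts and both knockout libraries beyond both NT libraries. The rule was met by 602 higher and 433 lower transcripts in EIF5A against NT. The plan also applied it to DOHH against NT, which was not done here.

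Coding counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with TMM factors, filterByExpr by group, all 6 libraries in 1 fit and Benjamini-Hochberg adjustment at 0.05. The 4 contrasts were EIF5A against NT, DOHH against NT, EIF5A against DOHH, and the mean of both knockouts against NT. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The same test was run on the 5' UTR counts and on the remainder. For the distribution between regions, the 5' UTR share was the 5' UTR count as a percent of 5' UTR plus coding counts, summed over 9728 transcripts with a mean of at least 10 such counts, with a 95% Wilson interval per library and an exact permutation test over libraries (two-sided). Intervals cover counting error only and treat each count as independent. Copies made by PCR are not independent molecules, so the intervals can be too narrow. Per transcript, an edgeR quasi-likelihood fit over both regions, with a term per library, tested whether the 5' UTR to coding ratio differed between groups.

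EIF5A and DOHH share the NT libraries. The correlation of their fold changes was therefore set beside 100 simulations of unchanged groups against those libraries, with the covariance, same-sign share and simulated values taken from differences of mean log2 scaled counts with a pseudocount of 2. In 20 simulated unchanged data sets fitted in full, at most 1 transcript was called. All these simulations gave the libraries of a transcript 1 common spread, without the wider spread of the NT pair.

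The tests were checked on simulated counts with the real means and library sizes. For EIF5A against NT over 9635 simulated transcripts, 70% of those changed 4-fold and 8.16% of those changed 2-fold were called, with 1 unchanged transcript called. The region test over 9695 simulated transcripts called 1% of those changed 4-fold and 13% of those changed 8-fold, so it detects few single transcripts at this design. These changes were placed only at transcripts with a mean of at least 11 counts in the 5' UTR, so recovery at lower counts was not measured. A share standardised to fixed transcript weights was tested on simulated data of 9829 transcripts whose composition differed in NT alone: the plain knockout minus NT difference was -2.94 points and the standardised one -0.0029 points.

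Alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom (limma 3.58.1), RLE or upper-quartile factors, library totals alone, no low-count filter, a mean of at least 50 counts, only the groups compared, the guide number as a block, and each library left out in turn. When a library was left out its group kept 1 library, whose spread was taken from the other groups. Alternatives added after seeing the data were 1 subtracted from each count, whole-transcript counts, libraries thinned to the lowest total, crossed guide numbers, a pseudocount of 0.5 or 10, and further settings of the region comparisons. Region summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.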

Results

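The data were ribosome footprint counts from HCT116 colon cancer cells in which EIF5A or DOHH had been targeted with Cas9, and from cells given NT guides. EIF5A encodes a translation factor that helps ribosomes pass slow sites in elongation and finish translation, and DOHH encodes the hydroxylase that completes hypusine, the modified lysine of eIF5A. The series title names ribosomal pausing and start codon selection, so the comparisons ask how footprints changed when the factor or its modifying enzyme was targeted, whether both had like effects, and how footprints were divided between 5' UTR and coding sequence. Each group held 2 libraries, 1 per guide. Coding counts summed to 4507604 and 3917979 in the EIF5A libraries, 4284248 and 4517752 in the DOHH libraries, and 2146624 and 2609560 in the NT libraries, so the NT values rest on the fewest counts. Over 9829 transcripts, 1718 (17.5%) had no 5' UTR count above 1 in any library.

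Across transcripts, log2 CPM (coding counts scaled to library size) correlated at r = 0.932 between the EIF5A libraries, 0.961 between the DOHH libraries and 0.897 between the NT libraries (transcripts are not independent replicates). The NT libraries also differed from each other by over 4-fold at 422 transcripts, against 196 for the EIF5A pair and 51 for the DOHH pair. NT 1 correlated with the 4 knockout libraries at 0.799 to 0.84 and NT 2 at 0.882 to 0.898, so NT 2 stood about as close to the knockout libraries as to NT 1.

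Targeting EIF5A changed coding footprint counts of 1080 of 9702 transcripts against NT, 623 higher and 457 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among them 142 were at least 4-fold higher and 65 at least 4-fold lower. These calls came from the fit of all 6 libraries, and the EIF5A and NT libraries alone gave 554. The deepest fall by the naming rule was that of ENST00000361739.1, with a log2 fold change of -4.57 (SE 0.52, edgeR adjusted p = 0.000297). Its coding counts were 30869 and 9367 in the NT libraries and 2482 and 1071 in the EIF5A libraries. ENST00000361899.2 fell with a log2 fold change of -4.23 (SE 0.53, edgeR adjusted p = 0.000297), from 8932 and 3292 counts in NT to 1051 and 324. Without NT 1 these falls were smaller, at -3.21 and -3.09. Neither transcript had a 5' UTR count above 1 in any library. Of the transcripts that rose, ENST00000356082.8 had a log2 fold change of 4.32 (SE 0.67, edgeR adjusted p = 0.00119), with 100 and 169 counts against 5 and 2 in NT. ENST00000372429.7 had a log2 fold change of 4.24 (SE 0.75, edgeR adjusted p = 0.00268), with 149 and 75 counts against 2 and 4. The NT counts of both lay close to the lowest deposited value of 1, so the sizes of these rises are uncertain.

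The direction split of EIF5A against NT depended on the scaling. With library totals alone, 745 were higher and 323 lower, and the median log2 fold change of all transcripts moved from 0.01 to 0.12. Every library weighed on the count, which was 489 without EIF5A 1, 263 without EIF5A 2, 606 without DOHH 1, 602 without DOHH 2, 651 without NT 1 and 2378 without NT 2. A fit of the EIF5A and NT libraries alone called 554. The main fit shared 1 spread over all 6 libraries, so the DOHH pair, in neither group compared, entered it. The SD of log2 differences was 0.415 within the DOHH pair, against 0.584 for EIF5A and 0.803 for NT. Whether the lower count without DOHH came from losing that tighter spread or from fewer libraries was not tested. With the guide number as a block 1386 were called, and 1985 with the DOHH numbers crossed in it, a pairing found from the data.

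**Figure D1:**
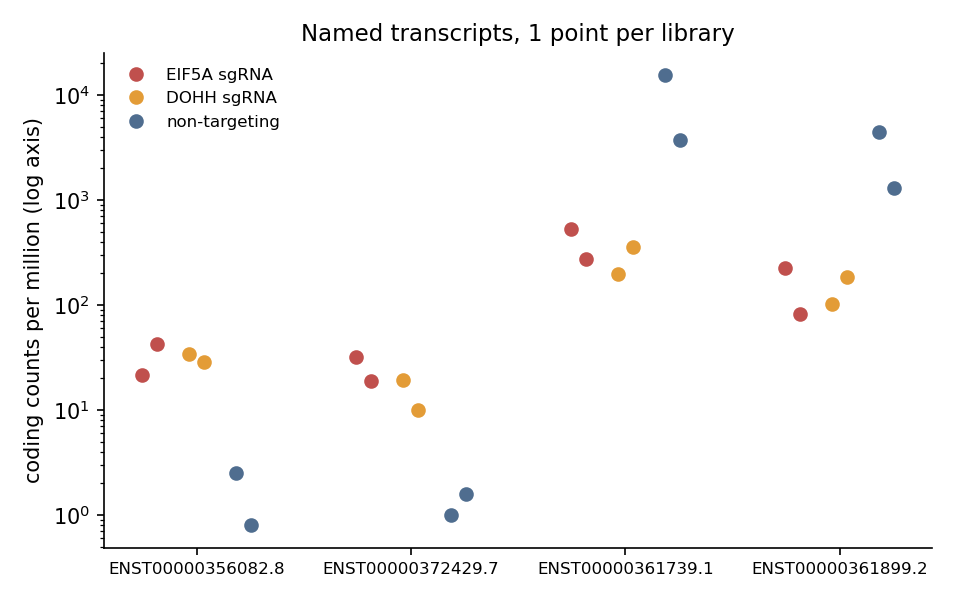
Coding CPM (log axis) of the 4 named transcripts, 1 point per library, with EIF5A in red, DOHH in orange and NT in blue. All 4 knockout libraries lie above both NT libraries for the first pair of transcripts and below both for the last pair, and the NT libraries of ENST00000361739.1 lie at 15300 and 3720 CPM.

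Targeting DOHH changed 1626 of 9702 transcripts against NT, 888 higher and 738 lower, of which 192 were at least 4-fold higher and 81 at least 4-fold lower (edgeR's quasi-likelihood test). The same named transcripts moved in the same directions. They had been picked for large changes in EIF5A against the same NT libraries, so this is not independent support. ENST00000361739.1 had a log2 fold change of -5.11 (SE 0.54, edgeR adjusted p = 6.17e-05), with 879 and 1642 counts in the DOHH libraries. ENST00000361899.2 had one of -4.31 (SE 0.53, edgeR adjusted p = 0.000163). Without NT 1 these were -3.75 and -3.18. ENST00000356082.8 was higher by 4.29 on the log2 scale (SE 0.67, edgeR adjusted p = 0.00101). ENST00000372429.7 was higher by 3.45 (SE 0.75, edgeR adjusted p = 0.0068). That last call ended without DOHH 1, at 2.88 and an edgeR adjusted p of 0.109, against 0.001 to 0.109 over all its alternatives. With library totals alone the split was 1104 higher and 562 lower, with a median shift of 0.11. The guide number as a block gave 1930 calls, and 2561 with the DOHH numbers crossed in it. The count was 152 without DOHH 1, 480 without DOHH 2, 889 without NT 1 and 2910 without NT 2.

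Taking both knockouts against NT, 2122 of 9702 transcripts changed, 1057 higher and 1065 lower, with edgeR's quasi-likelihood test. With library totals alone 1275 were higher and 803 lower. This count was 1392 without EIF5A 2, 839 without DOHH 1, 1231 without DOHH 2 and 977 without NT 1.

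No transcript of 9702 differed between EIF5A and DOHH with edgeR's quasi-likelihood test (0 past the threshold, smallest edgeR adjusted p 0.0717). At an unadjusted p under 0.05, 604 differed, where 485 would arise by chance. The fit shared 1 spread over all 6 libraries, including the NT pair, which differed most from each other. Recovery was not simulated for this contrast, so 0 calls do not show that the knockouts are alike. DESeq2 called 38 and limma voom 14. edgeR called 17 with the guide number as a block and 44 with the DOHH numbers crossed in it, a pairing found from the data. edgeR called 41 in a fit of the EIF5A and DOHH libraries alone, 39 without NT 1 and 21 without NT 2.

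Fold changes of the knockouts against NT correlated across 9702 transcripts at r = 0.83. Unchanged groups sharing the same NT libraries gave a mean of 0.53 and at most 0.55 in 100 simulations. The covariance was 0.728 against a simulated 0.142, a difference of 0.586. Of the transcripts, 83.8% had the same sign in both comparisons, against 67.4% in the simulations. Both tests called 457 transcripts higher and 300 lower, and 0 in opposite directions, where independent lists would share 57 and 34.8. In 20 simulated fits of unchanged groups sharing the NT libraries, at most 1 transcript was called in either comparison, and at most 1 in both. With so few calls these fits could not show a larger overlap, so they are no reference for it. The numbers for independent lists also leave the shared NT libraries out of account. The simulations gave all groups the same spread per transcript. The SD of log2 differences was 0.803 between the NT libraries, 0.584 between the EIF5A and 0.415 between the DOHH libraries. Simulated values can therefore understate what the shared NT libraries alone produce, and part of the excess may come from those libraries. With a different NT library for each knockout r was 0.51 or 0.42, a setting that also leaves 1 NT library per comparison. No simulation was run for this setting, so the 0.53 of shared NT libraries is no reference for it.

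**Figure D2:**
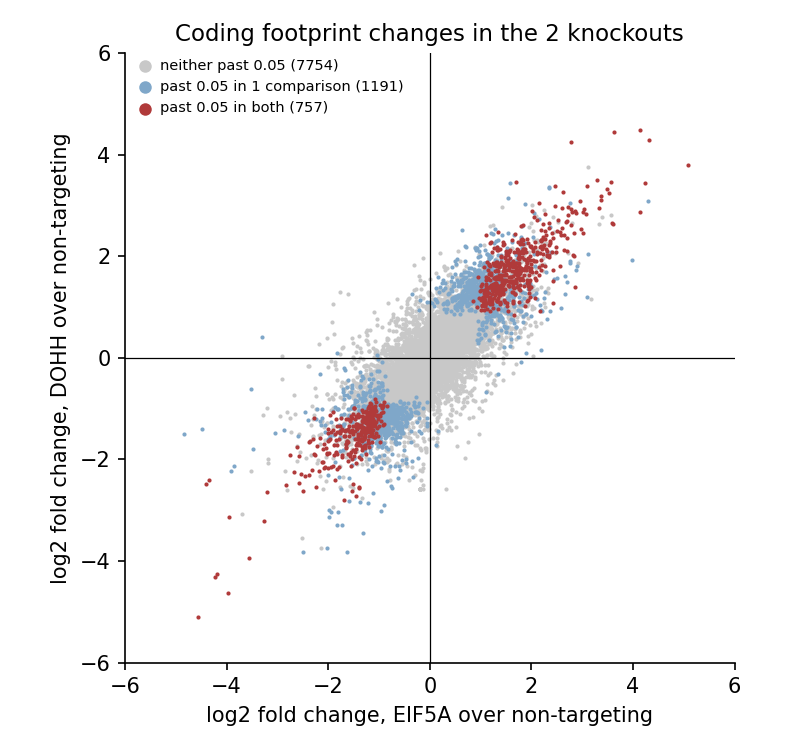
Log2 fold change of coding counts per transcript, EIF5A over NT on the x axis and DOHH over NT on the y axis. Red points (757) passed an edgeR adjusted p of 0.05 in both comparisons, blue points (1191) in 1 and grey points (7754) in neither, and no red point lies in an opposite-sign quadrant.

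Footprints in 5' UTRs, which include those of ribosomes at upstream start sites, made up a smaller share in the knockout libraries than in the NT libraries. The 5' UTR share was 7.8% and 9.08% in the EIF5A libraries, 8.77% and 7.47% in the DOHH libraries, and 10.6% and 11.2% in the NT libraries, with 95% Wilson intervals reaching at most 0.039 points to either side. Group means were 8.44% ± 0.91 for EIF5A, 8.12% ± 0.92 for DOHH and 10.9% ± 0.44 for NT (SD, n = 2 each). All 4 knockout libraries lay below both NT libraries, and the mean difference was -2.63 percentage points (exact permutation test, two-sided p = 0.0667, the smallest that 15 assignments allow). For EIF5A against NT the difference was -2.47 points and for DOHH against NT -2.79 points (exact permutation p = 0.333 each, the smallest possible with 2 against 2). EIF5A minus DOHH was 0.323 points, less than the spread between libraries of a group (exact permutation p = 0.667). This permutation test cannot reach 0.05 in any of these comparisons.

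The order held in each of 5 classes of transcript abundance, from a mean of 16.8% in knockouts against 21.3% in NT at 10 to 50 counts, to 6.74% against 9.07% at 1000 counts or more. These classes used counts as deposited and were not repeated with 1 subtracted. The lowest value of 1 per region can raise the share most at low counts and in the shallower NT libraries. With each transcript given the same weight in all libraries, the difference was smaller, -1.58 points, with a standard error of 0.849. The standard error was 0.101 with the DOHH guide numbers crossed as a block, a pairing found from the data. This setting also subtracted 1 from each count and kept only 8557 transcripts with at least 10 counts left in every library. The plain share was not taken on those transcripts, so the smaller difference cannot be laid to the weights alone. The highest knockout share was then 9.2% and the lowest NT share 9.41%, and another split of the libraries gave a larger difference (exact permutation test, two-sided p = 0.133).

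**Figure D3:**
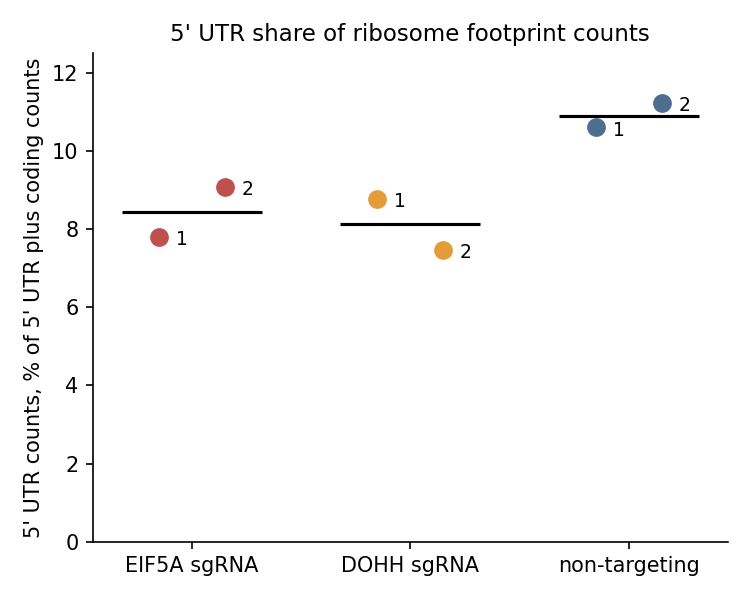
Share of 5' UTR counts in 5' UTR plus coding counts, in percent, for each library (points, numbered by guide) with the group mean (bars). The 4 knockout libraries lie between 7.47% and 9.08%, and the NT libraries at 10.6% and 11.2%.

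Per transcript, the 5' UTR to coding ratio passed the edgeR test at 0 of 9728 transcripts in each comparison. At an unadjusted p under 0.05, EIF5A against NT gave 888 (232 higher, 656 lower) and DOHH against NT 831 (179 higher, 652 lower), where 486 would arise by chance. EIF5A against DOHH gave 392, and both knockouts against NT 1022 (198 higher, 824 lower). These tests used counts as deposited, including transcripts whose 5' UTR stood at 1 in every library. At those, larger coding counts alone give a lower ratio, and coding totals were larger in the knockouts. Part of the excess of lower ratios can therefore follow from depth, and no split was taken with 1 subtracted. limma on log2 ratios also called 0 transcripts in each comparison. The median log2 change of the ratio was -0.53 for EIF5A and -0.52 for DOHH. For EIF5A it was -0.31 without EIF5A 1 and -0.88 without EIF5A 2. At transcripts with a mean of at least 11 counts in the 5' UTR it was -0.32 for EIF5A and -0.33 for DOHH. It was -0.22 for each after 1 was subtracted from every count, and 0.05 for each when regions were scaled separately, which removes a shift shared by all transcripts.

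Counts in the 5' UTR alone changed at 179 of 5251 transcripts in EIF5A against NT (99 higher, 80 lower) and at 151 in DOHH against NT (75 higher, 76 lower) with edgeR's quasi-likelihood test. Both knockouts against NT gave 308 (125 higher, 183 lower). Between EIF5A and DOHH 0 of these passed, with 338 at an unadjusted p under 0.05, where 263 would arise by chance. Of transcripts tested in both regions, 74 were called in both for EIF5A and 88 for DOHH, where independent lists would share 21.6 and 27.8. All of these moved in the same direction in the 5' UTR and the coding sequence. For both knockouts against NT, 172 were called in both regions, 170 of them in the same direction, where independent lists would share 74. The 2 regions belong to the same transcripts and libraries, so a change in transcript level moves both. Independent lists are therefore a weak reference, and these numbers also ignore direction. In the remainder, 1411 transcripts could be tested. EIF5A against NT called 1 there, DOHH against NT 7, both knockouts against NT 10 and EIF5A against DOHH 0 (edgeR). At an unadjusted p under 0.05 these gave 153, 134, 177 and 58, where 71 would arise by chance. The remainder made up 1.59% ± 0.25 of counts in EIF5A, 1.49% ± 0.033 in DOHH and 2.0% ± 0.38 in NT (SD, n = 2 each), and 1 EIF5A library lay above NT 2.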

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

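The settings with 1 subtracted, whole-transcript counts, thinned libraries, crossed guide numbers, other pseudocounts and added region settings were chosen after seeing the data. All 152 values of the 4 named transcripts kept their direction and 151 stayed past the threshold, all but the DOHH value without DOHH 1 in the report. These transcripts were picked for large changes past the threshold against the same NT libraries, so this stability was largely set by the choice. With all 6 libraries and guide numbers uncrossed, every count against NT stayed within 1.5 times of the reported one. A fit of 2 groups alone called 554 for EIF5A against NT and 1584 for DOHH against NT; the cause was not tested. With a library left out in turn, counts ranged from 263 to 2378 for EIF5A against NT, 152 to 2910 for DOHH against NT, 839 to 3060 for both against NT and 0 to 39 for EIF5A against DOHH. Counts against NT rose only slightly or fell without a knockout library, fell without NT 1 and rose without NT 2; the cause was not tested. EIF5A against DOHH called 38 with DESeq2, 41 with only those groups, 14 with limma voom and 1 with whole-transcript counts, and the cause was not tested. The correlation of fold changes ranged from 0.642 to 0.894 with a library left out, and was 0.513 and 0.424 with 1 NT library for each knockout, which ends the sharing and leaves fewer controls. The 5' UTR share difference of DOHH against NT was -1.97 points without the 100 transcripts with most 5' UTR counts. With fixed transcript weights it was -1.59 points for EIF5A, -1.57 for DOHH and -1.58 for both. With a library left out, the share differences ranged from -3.11 to -1.83, -3.44 to -2.14 and -2.94 to -2.32 points for EIF5A, DOHH and both against NT, and from -0.329 to 0.975 for EIF5A against DOHH. The region test called 0 transcripts under all of its alternatives.

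Guide numbers name different guides and do not pair samples. Same-numbered deviations correlated at -0.27 between EIF5A and DOHH, 0.26 between EIF5A and NT and -0.18 between DOHH and NT. With the number as a replicate block, 1386, 1930 and 2347 transcripts were called for EIF5A, DOHH and both against NT, and 17 for EIF5A against DOHH. With the DOHH numbers crossed in the block, 1985, 2561, 2961 and 44 were called. Each set of that block holds 1 library of each group, so it cannot move the fixed-weight share differences of -1.59, -1.57 and -1.58 points. It changed only the standard error, which was 0.101 in place of 0.849 for both knockouts against NT. Gene list tests and the setting without gene classes were not run, and no pseudocount entered the count tests. The covariance difference was 0.622 and 0.473 with a pseudocount of 0.5 and 10. The 5' UTR stood at the lowest value for 25.2% to 45.8% of transcripts per library, which limits the region test there.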

Other observations

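All tests in this part were chosen after the result was seen. Among 7572 transcripts with a mean of at least 50 coding counts, 4 had the deepest falls in the mean of both knockouts against NT. Their log2 fold changes, against the same NT libraries, lay between -4.57 and -3.55 in EIF5A and between -5.11 and -3.94 in DOHH. The 4 took 2.34% of all coding counts in NT 1 and 0.638% in NT 2, against 0.115% and 0.0523% in the EIF5A libraries and 0.0439% and 0.0811% in the DOHH libraries. None of the 4 had a 5' UTR count above 1 in any library, and 3 had nothing above 1 outside the coding sequence. Without gene names and the annotation, it was not checked whether the 4 have an annotated 5' UTR or are mitochondrially encoded. Transcripts without 5' UTR counts made up 15.8% of those considered. Their share was 14.3% among all those called lower in the mean of both knockouts against NT and 14.3% among those called higher. After the 4, the next fall was -2.67, against -3.74 for the fourth.

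Among 4229 transcripts with a mean of at least 11 counts in the 5' UTR, both NT libraries had a higher 5' UTR share than all 4 knockout libraries at 780 and a lower one at 241, where chance gives 282 (6.7%) each. Other choices of 2 libraries gave up to 457 above the rest. DOHH 2 and EIF5A 1 were together below the rest at 752, so the low shares of those libraries were about as frequent as the high shares of NT.

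Of the technical explanations for the lower 5' UTR share in the knockout libraries, 3 were weighed. The count of 1 added to each region, or the floor at 1, does not account for it: the difference was -2.51 points with 1 subtracted from each count, beyond the 95% limit of -2.18, and -2.56 points with values of 1 set to 0. A few transcripts with most 5' UTR counts do not account for all of it, though narrowly: without the top 100 the difference was -1.86 points against a limit of -1.84. The fixed-weight setting also subtracted 1 and used 8557 transcripts, so its smaller difference cannot be laid to the weights alone. A change in which transcripts carry the footprints may account for part. With fixed weights the difference was -1.58 points, short of the limit of -2.7. That limit takes the libraries as unpaired: EIF5A 1, DOHH 2 and NT 1 deviated together in coding counts, and within these and the remaining libraries the differences ran from -1.76 to -1.43 points, which argues against composition as the whole cause only if the sets, found from the data, are real. As deposited, the remainder share was also lower in the mean of both knockouts. The difference was -23.1% of the NT mean, against -24.1% for the 5' UTR share. The remainder share was taken of all counts over the transcript and was not repeated with 1 subtracted. The lowest value of 1 can therefore make up part of its fall. For the remainder the exact permutation test gave a two-sided p of 0.133. A fall outside the coding sequence at large was therefore not told apart from one in 5' UTRs. An effect of losing eIF5A or its modification on 5' UTR footprints stays open and was not tested apart from these explanations.

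Isolated counts were larger in EIF5A 1. Where the remainder of a transcript stood at 1 in the other 5 libraries, the median isolated count above 1 was 9 in EIF5A 1, against 1 in EIF5A 2, 3 in both DOHH libraries and in NT 1, and 5 in NT 2. Copies of 1 footprint counted separately may be the source: in the 5' UTR, a region apart, the median was 8.0 in EIF5A 1 and at most 4.0 elsewhere. Greater depth of that library does not account for it, since its isolated count was 3.0 times that of DOHH 2 at 1.0 times the total count. No biological explanation was tested.

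The NT libraries differed from each other more than those of other groups, with an SD of log2 differences of 0.803 over 7572 transcripts, against 0.415 for DOHH and 0.584 for EIF5A. Their lower depth is an unlikely cause, since the DOHH libraries thinned to the NT totals gave 0.436. Whether the 2 NT guides or their cultures differed stays open and was not tested.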
